A study of Homo sapiens with 6 samples.

How the data were processed

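Gene expression was measured on 6 single-colour Illumina bead arrays hybridised with biotin-labelled total RNA from OVSAYO, an ovarian cancer cell line. Per the labels' protocols, cells were transfected with Lipofectamine, harvested 48 h later and extracted with a kit that keeps small RNA. The labels place 3 arrays in the mir-100 mimic group and 3 in the control mimic group, and describe them as biological replicates. A mimic is a synthetic double-stranded RNA that supplies a mature microRNA, and the control mimic is based on a worm microRNA with little identity to human ones. The dose of the mimics is not given in the sources used here, since the stated 66 nM refers to a hairpin inhibitor. Mock-transfected cells and inhibitor-treated cells were not analysed here.

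The authors deposited 1 scanner table per array with the mean bead intensity of each of 48803 probes, on a linear scale and without background subtraction or scaling between arrays, as the values showed. The deposited detection score of each probe runs from 0 to 1 and is high for bright probes, so 1 minus the score was used as the detection p. The deposited tables also give the number of beads behind each mean, which had a median of 41 or 42 on every array. BeadStudio is named in the submitters' processing notes, with a version not given in the sources used here. A second table holds the authors' processed intensity values for the same arrays. Within each array these were a monotone function of the scanner intensity, brought to the distribution of mir-100 mimic replicate 1, with a median of 46.2 in each array. They are linear, uncentred intensities, and the method that made them is not given in the sources used here.

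The scanner tables and the table of processed values carry different probe identifiers. They were paired through the values of all 6 arrays compared to 4 decimals, and 48803 of 48803 probes matched one to one. Gene symbols came from the platform annotation given for the processed table: 28098 probes had 1 symbol, 13 had several and 20692 had none. Of the first, 28059 had a gene identifier in the RefSeq gene table of assembly GRCh38.p14, which was used for names only and changed 0 symbols. The probes named 18852 distinct genes. No gene was named from a probe with several symbols, and no coordinates are given because the build behind the probes is not given in the sources used here.

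Intensities were background-corrected, offset by 16, quantile-normalized and put on the log2 scale with neqc of limma 3.58.1 in R 4.3.3, which infers the negative controls from the detection p. Probes with a detection p under 0.05 on at least 3 of 6 arrays were kept, 21361 in all. Each gene was represented by its brightest kept probe, which left 12039 genes. Of these, 3203 had several detected probes, and 62 had probes that passed the test in opposite directions. The mir-100 mimic group was compared with the control mimic group by lmFit and eBayes of limma over all 6 arrays without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. Prior degrees of freedom were 8.003. Log2 differences are mir-100 mimic minus control mimic, and folds are their antilogs. Where every array of a group lay below the detection threshold, the fold is given as a lower bound: the mean log2 intensity of the detected group was set against the mean, over the arrays of the other group, of the higher of the lowest detected intensity and the probe's own. Probe pairing used Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and array weights used statmod 1.5.0.

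The design, the grouping, the alternatives other than those named in the closing part, the rule for named genes and 18 gene lists were fixed before the data were examined. The lists held 533 entries of 527 genes, with 6 genes in more than 1 list, and came from general knowledge of mTOR signalling, targets of the miR-99/100 family, stress and transfection responses, cell division and cell types. Each list was tested with camera of limma at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 18 lists, and again with an estimated correlation. Camera compares a list with the other genes. Fry, which asks whether the members of a list move on balance in 1 direction without reference to other genes, was run beside it. The named genes were the 10 with the largest rise and the 10 with the largest fall among genes that passed and whose groups did not overlap, MTOR, and the up to 4 members of each list with the smallest p. Predicted loci were to be passed over, and 0 were.

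The model and the list test were tested on simulated data for this comparison, with 12039 genes and 200 changed genes in each of 20 simulations. The model recovered 39% of genes changed 1.25-fold, 98.6% at 1.5-fold, and 100% at 2-fold and at 3-fold. Of all its calls in the simulations, 6.17% were false, somewhat more than the nominal rate. The list test recovered 1 shifted list of 1. The simulated genes varied independently, were drawn on the normalized scale, and few of them changed. In the data 51.4% of genes passed, and the estimated correlation within a list reached 0.358, for heat shock genes. The simulated rates therefore need not hold for the data, and the simulation cannot test the preset correlation.

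The alternatives tried were no background correction, median scaling of arrays, the authors' processed values, no filter or a stricter filter on dim probes, the mean of a gene's probes, an intensity trend in the variance, array weights, the replicate number as a block, a minimum fold and the omission of each array in turn. The number of arrays limits the precision of every value. The array or slide position was not used as a block because none is named in the sources used here. The sample titles carry running numbers of unstated meaning, and those of the mir-100 mimic arrays all precede those of the control mimic arrays. If they mark position or order, these cannot be told apart from the group. A planned test of genes with a seed site for mir-100 or for the control mimic was not run, since it needs 3' untranslated sequences, which were not used here. The level of mir-100 itself was not analysed here.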

Results

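Transcript levels were profiled in OVSAYO cells, a line from ovarian clear cell carcinoma, 48 h after transfection with a mir-100 mimic (3 arrays) or a control mimic (3 arrays). Of 48803 probes per array, between 20572 and 21945 were detected. The mean scanner signal was 285, 304 and 262 on the mir-100 mimic arrays and 245, 228 and 237 on the control mimic arrays, so the mean of every mir-100 mimic array was above that of every control array. The median signals did not separate the groups, at 46.2, 47.0 and 46.1 against 45.1, 45.8 and 46.4. After normalization, arrays were correlated across the 12039 genes tested, with 1 probe per gene. The r was 0.995 to 0.997 for arrays of the same group and 0.973 to 0.982 for arrays of different groups. Genes are not independent replicates. The first principal component held 82.9% of the variance and separated the groups, with scores of 25.8, 27.6 and 19.8 for mir-100 mimic replicates 1, 2 and 3 and of -26.4, -24.1 and -22.6 for the control arrays.

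The comparison asked which transcripts differ when mir-100, a microRNA that the submitters describe as under-expressed in ovarian cancer, is supplied to these cells. The largest rise was in PLAUR, the receptor for the protease urokinase, from a normalized log2 intensity of 5.75 ± 0.20 to 9.10 ± 0.31 (mean ± SD, n = 3 per group here and throughout), a 10.2-fold difference with a limma adjusted p of 1.95e-08. PLAU, which encodes urokinase itself, rose 5.32-fold from 10.30 ± 0.07 to 12.71 ± 0.20. IL6, an inflammatory cytokine, rose 4.85-fold from 6.80 ± 0.08 to 9.08 ± 0.11, and AXL, a receptor tyrosine kinase, rose 4.54-fold from 7.03 ± 0.07 to 9.22 ± 0.08. The largest fall was in MMP10, a secreted matrix metalloproteinase, from 9.36 ± 0.15 to 6.45 ± 0.35, which was 7.52-fold lower with a limma adjusted p of 5.33e-08.

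The other genes with the largest rise were FABP5, a fatty acid-binding protein (4.32-fold), IL27RA, a cytokine receptor subunit (4.23-fold), CDA, cytidine deaminase (3.93-fold), PTGS2, an inducible enzyme of prostaglandin synthesis (3.69-fold), FXYD5, a regulator of the sodium pump (3.69-fold), and PCOLCE2, an enhancer of procollagen processing (3.67-fold). Of the 2 other detected probes of FXYD5, 1 passed in the same direction and 1 went the opposite way without passing. After MMP10, the largest falls were in VTCN1, an inhibitory surface protein of the B7 family (6.94-fold lower), LUM, the proteoglycan lumican (6.78-fold lower), SLC2A12, a sugar transporter (6.22-fold lower), FLG, filaggrin (6.04-fold lower), and HGD, an enzyme of tyrosine breakdown (5.94-fold lower). SOSTDC1, a secreted antagonist of bone morphogenetic protein signalling, was 5.94-fold lower. TCN2, a carrier of cobalamin, was 5.56-fold lower, EPHA4, an ephrin receptor, 5.20-fold lower, and WDR72, a WD-repeat protein, 4.96-fold lower. The standard errors of these 20 log2 differences lay between 0.08 for LUM and 0.15 for MMP10, and the largest limma adjusted p was 2.80e-07, for FABP5.

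Of 12039 genes tested with limma, 6190 passed the adjusted threshold (51.4%), 3150 higher and 3040 lower in the mir-100 mimic arrays. With a fold of at least 2, 128 genes were higher and 311 lower, against 58 and 184 without background correction and 72 and 194 with the authors' processed values. The 3 values of one group did not overlap the 3 of the other for 7032 genes (58.4%, against 10% by chance). Scaling each array to its median in place of quantile normalization gave 4749 genes higher and 1461 lower, with 358 and 162 at a fold of at least 2, and moved the median difference of all genes from 0.01 to 0.17 on the log2 scale. Values given below with median scaling include this shift, which was not the same for every gene. Between 42.15% and 44.97% of an array's probes were detected, so the median over all its probes falls among undetected probes. Scaling to it can leave a difference in brightness between arrays in the detected genes. The mean scanner signal was 262 to 304 on the mir-100 mimic arrays and 228 to 245 on the control arrays. Counts and calls that move with median scaling may reflect this difference, whose cause was not tested.

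**Figure D1:**
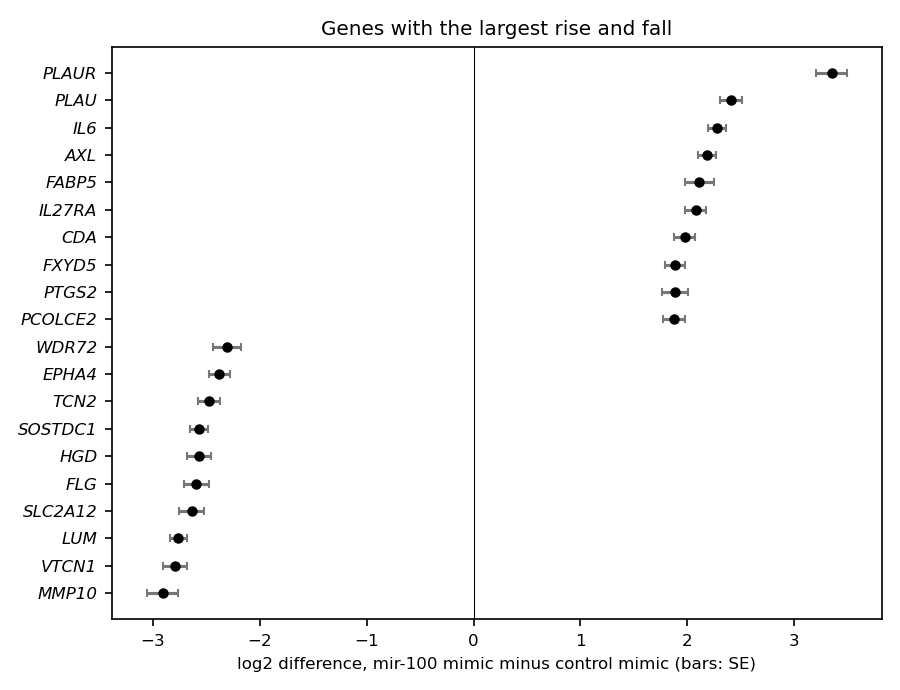
The horizontal axis is the log2 difference, mir-100 mimic minus control mimic, for the 10 genes with the largest rise and the 10 with the largest fall. Points are differences of the group means (n = 3 per group) and bars are standard errors, and the values run from 3.35 for PLAUR to -2.91 for MMP10.

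MTOR, the kinase of the growth-regulating mTOR complexes and a reported target of mir-100, was 1.87-fold lower in the mir-100 mimic arrays. Its normalized log2 intensity was 9.29 ± 0.08 against 10.19 ± 0.11, and its scanner signal was 713, 745.9 and 691.3 in mir-100 mimic replicates 1 to 3 and 1185, 1032 and 959.4 in the controls. EPDR1, an ependymin-related glycoprotein, fell 3.84-fold, BMPR2, a bone morphogenetic protein receptor, 3.12-fold, FGFR3, a fibroblast growth factor receptor, 2.75-fold, and SMARCD1, a subunit of the SWI/SNF chromatin remodelling complex, 1.98-fold. The 1 other detected probe of SMARCD1 was also lower but did not pass. These 5 genes belong to a list of reported or predicted targets of the miR-99/100 family, of which 35 were measured, 20 fell, 1 rose and 14 did not pass. Adjusted over the list alone, 21 fell and 1 rose. The gene that rose was PLK1, a mitotic kinase, with a log2 difference of 0.52. PLK1 is named here because it was the exception, after its value was seen, and it also belongs to the G2/M and mitosis list. The MTOR difference of -0.90 (SE 0.09) had a limma adjusted p of 6.32e-06, and a two-sided exact permutation test on its 6 values gave p = 0.1, the smallest that 3 against 3 arrays allow. With median scaling the MTOR difference was -0.57.

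The median log2 difference of the target list was -0.46, and the list lay below other genes by limma's camera with an adjusted p of 3.54e-06, but with an adjusted p = 0.279 with an estimated correlation. With median scaling the list median was -0.21, with 17 members lower and 1 higher (limma camera adjusted p = 5.40e-07). It was -0.29 without background correction and -0.30 with the authors' processed values. Without a detection filter it was -0.19 over 44 measured members. The list passed camera in 16 of 17 alternatives, all but the estimated correlation.

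**Figure D2:**
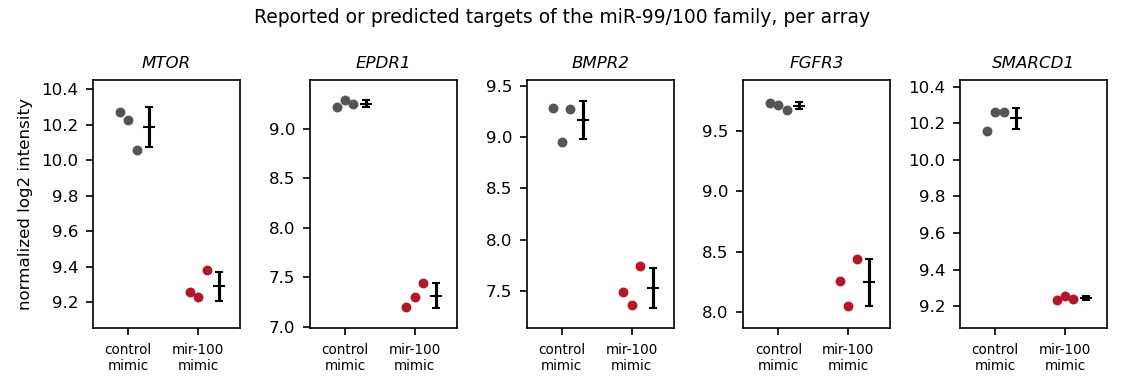
Each panel shows 1 gene of the miR-99/100 target list, with normalized log2 intensity on the vertical axis, a point per array, and the mean ± SD of each group (n = 3) beside the points. In each of the 5 panels the mir-100 mimic arrays lie below every control mimic array, as for MTOR at 9.29 against 10.19.

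Among 35 measured members of the mTOR pathway list, 8 rose, 8 fell and 19 did not pass, with 8 and 8 adjusted over the list alone. DEPTOR, an inhibitory partner of mTOR, was 4.18-fold lower, from 7.51 ± 0.13 to 5.45 ± 0.02, and ULK1, a kinase that starts autophagy, was 2.00-fold lower. EIF4EBP1, a translation repressor that mTOR phosphorylates, was 2.08-fold higher. The list had a median of -0.02 and did not pass camera (limma adjusted p = 0.591, and 0.689 with an estimated correlation). With median scaling its median was 0.20, with 13 members higher and 6 lower, and without control mimic replicate 2 there were 5 higher and 8 lower. The list shares MTOR, AKT1, RPTOR and RRAGD with the target list.

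Most measured genes of the DNA replication list and of the mitosis list rose. Of 30 measured genes of the G1/S and DNA replication list, 28 rose and 0 fell, and adjusted over the list alone 29 rose and 1 fell. CDT1, a licensing factor for replication origins, rose 2.11-fold, RRM2, a subunit of ribonucleotide reductase, 2.06-fold, CHAF1B, a histone chaperone subunit, 1.68-fold, and RFC5, a clamp loader subunit, 1.63-fold. The median of the list was 0.44 (limma camera adjusted p = 1.52e-08, and adjusted p = 0.206 with an estimated correlation). Of 35 measured genes of the G2/M and mitosis list, 27 rose, 0 fell and 8 did not pass, with the counts of 27 and 0 also adjusted over the list alone. AURKB, a mitotic kinase, rose 1.78-fold, CDC20, an activator of the anaphase-promoting complex, 1.84-fold, KIF2C, a kinesin, 1.72-fold, and CCNA2, cyclin A, 1.78-fold. The median of the list was 0.42 (limma camera adjusted p = 2.23e-07, and adjusted p = 0.312 with an estimated correlation). With median scaling the medians of the 2 lists were 0.75 and 0.71.

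Genes of cholesterol and fatty acid synthesis fell, 22 of 25 measured, with 0 higher and 3 not passing. Adjusted over the list alone, 22 fell and 1 rose. HMGCS1, an early enzyme of the mevalonate pathway, fell 2.75-fold from 10.63 ± 0.06 to 9.17 ± 0.02, TM7SF2, a sterol reductase, 3.12-fold, SC5D, a sterol desaturase, 2.73-fold, and SCD, a fatty acid desaturase, 2.08-fold. The median was -0.46 (limma camera adjusted p = 4.29e-07, and adjusted p = 0.279 with an estimated correlation). With median scaling it was -0.18, with 11 members lower and 2 higher (limma camera adjusted p = 1.56e-06). The list passed camera in 16 of 17 alternatives, all but the estimated correlation.

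Of 35 measured genes of the lysosome and autophagy list, 20 fell, 4 rose and 11 did not pass, and the counts adjusted over the list alone were also 20 and 4. ATP6AP1, an accessory subunit of the proton pump that acidifies lysosomes, fell 3.78-fold, NEU1, a lysosomal sialidase, 3.00-fold, LAMP1, a lysosomal membrane glycoprotein, 1.89-fold, and GABARAPL1, a protein of autophagosome membranes, 1.80-fold. The median was -0.34 (limma camera adjusted p = 0.000781, and adjusted p = 0.289 with an estimated correlation). With median scaling it was -0.03, with 10 members lower and 7 higher, and the list still lay below other genes (limma camera adjusted p = 0.0103). Without control mimic replicate 2 or 3, 20 members were lower and 2 higher. The list passed camera in 16 of 17 alternatives, all but the estimated correlation.

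Of 16 measured genes of the NF-kB and inflammation list, 9 rose, 2 fell and 5 did not pass, and adjusted over the list alone 9 rose and 3 fell. Beside IL6, IER3, an immediate early response gene, rose 2.10-fold, and SOD2, the mitochondrial superoxide dismutase, 1.82-fold. TNF, a cytokine, rose 1.97-fold from 4.88 ± 0.12 to 5.86 ± 0.03. The 2 that fell were CCL20 (1.59-fold) and IL1A (1.24-fold), named after their values were seen. The median was 0.31 (limma camera adjusted p = 0.0137, and adjusted p = 0.28 with an estimated correlation), and 0.58 with median scaling. With median scaling 10 members were higher and 1 lower, and without mir-100 mimic replicate 1 these counts were 9 and 1. The interferon response list, with 24 measured members, had 7 higher, 5 lower and 12 not passing, and 7 and 5 adjusted over the list alone. IFITM1 and IRF1, an antiviral membrane protein and a transcription factor, rose 1.94-fold and 1.69-fold, SP110, a nuclear body protein, rose 1.76-fold, and PARP9, an ADP-ribosyltransferase family member, fell 1.56-fold. That list did not pass camera (limma adjusted p = 0.698), and its median of -0.01 differed in sign from its mean of 0.07 and from the upward direction of the test. With median scaling the interferon list had 8 members higher and 3 lower and a median of 0.16.

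**Figure D3:**
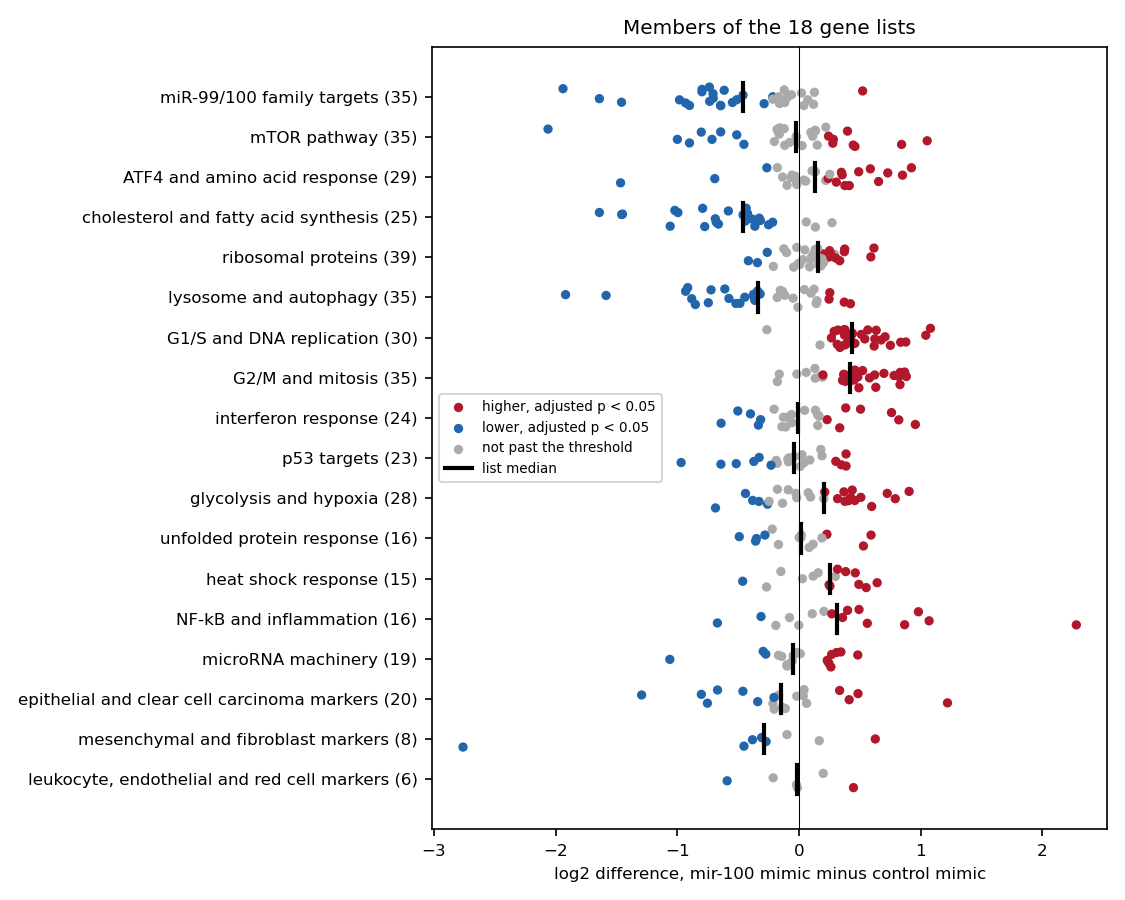
The horizontal axis is the log2 difference, mir-100 mimic minus control mimic, and each line of points holds the measured members of 1 of the 18 gene lists, with their number in brackets. Red and blue points are genes higher or lower at a limma adjusted p under 0.05, grey points did not pass, and black bars are list medians, which run from -0.46 for the miR-99/100 targets to 0.44 for G1/S genes with quantile normalization.

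The ribosomal protein list had 12 of 39 measured members higher and 3 lower, with 7 and 3 adjusted over the list alone. RPL28, RPL29 and RPL14, proteins of the large ribosomal subunit, rose 1.53-fold, 1.51-fold and 1.30-fold, and RPL22, another, fell 1.33-fold, a fall that did not pass with median scaling. Its median of 0.15 did not pass camera (limma adjusted p = 0.0584), but passed with median scaling (0.00297, with 31 members higher and 0 lower) and with the authors' processed values (0.000449). It passed in 8 of 17 alternatives, with adjusted p from 0.000449 to 0.712, among them those without mir-100 mimic replicate 3 (0.0290) and without control mimic replicate 3 (0.0325). With cyclic loess normalization, 5 members were higher and 5 lower with a median of 0.003. Without mir-100 mimic replicate 1 the counts were 8 higher and 1 lower, without replicate 2 they were 6 and 3, and without control mimic replicates 1 and 2 they were 7 and 2, and 6 and 4. Of 15 measured heat shock genes, 8 rose and 1 fell, with 8 and 2 adjusted over the list alone. The chaperone genes HSPE1, HSP90AB1, HSPA8 and DNAJB1 rose 1.56-fold, 1.47-fold, 1.41-fold and 1.38-fold. The heat shock list also did not pass (limma camera adjusted p = 0.0812) and passed in 7 of 17 alternatives, with adjusted p from 0.0189 with median scaling to 0.689 with an estimated correlation, among them that without mir-100 mimic replicate 3 (0.0264). Without mir-100 mimic replicate 1, 5 heat shock genes were higher and 2 lower (0.133), and without replicate 2 the counts were 6 and 2 (0.118).

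In the ATF4 and amino acid response list, 12 of 29 measured members rose and 3 fell, with the counts of 12 and 3 also adjusted over the list alone. MTHFD2, a mitochondrial folate enzyme, rose 1.90-fold and TRIB3, a stress-induced pseudokinase, 1.80-fold. VLDLR, a lipoprotein receptor, fell 2.76-fold and SLC7A11, a cystine transporter, 1.62-fold. In the glycolysis and hypoxia list, 14 of 28 rose and 5 fell, with 15 and 6 adjusted over the list alone. PFKP, a phosphofructokinase, rose 1.87-fold, ADM, adrenomedullin, 1.73-fold, and PGAM1, a phosphoglycerate mutase, 1.65-fold, and BHLHE40, a transcription factor, fell 1.61-fold. Neither list passed camera (limma adjusted p = 0.121 and 0.136), and both passed with median scaling (0.0209 and 0.0331) but in none of their other alternatives, where adjusted p reached 0.492 and 0.312. Their counts with median scaling were 21 higher and 2 lower, and 16 higher and 1 lower.

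Of 23 measured p53 targets, 4 rose and 6 fell, with 4 and 6 adjusted over the list alone. TP53INP1, a p53-induced nuclear protein, fell 1.96-fold, SPATA18, a mitochondrial quality control gene, 1.56-fold, and XPC, a DNA damage sensor, 1.43-fold, while FAS, a death receptor, rose 1.31-fold. The p53 list median was -0.04 and was 0.25 with median scaling, where 11 members were higher and 2 lower and the call for XPC was lost. Without mir-100 mimic replicate 1 or 2, 2 p53 targets were higher and 4 lower. Of 16 unfolded protein response genes, 3 rose and 4 fell, with 3 and 4 adjusted over the list alone. MANF, a secreted protein of the endoplasmic reticulum, and XBP1, a transcription factor, rose 1.51-fold and 1.44-fold, and the chaperones HYOU1 and HSPA5 fell 1.41-fold and 1.28-fold, falls that did not pass with median scaling. The unfolded protein response counts were 8 higher and 0 lower with median scaling, 3 and 2 without mir-100 mimic replicate 2, and 2 and 2 without control mimic replicate 1 or 2. Of 19 genes of the microRNA machinery, 7 rose and 3 fell, with 7 and 3 adjusted over the list alone. TNRC6B, a partner of Argonaute proteins, fell 2.09-fold, and XPO5, TARBP2 and DICER1, which export or process microRNA precursors, rose 1.40-fold, 1.27-fold and 1.24-fold. The microRNA machinery counts were 3 higher and 3 lower without mir-100 mimic replicate 1 or 2, 4 and 2 without control mimic replicate 1, 4 and 3 without control mimic replicate 2, and 8 and 1 with median scaling. The 3 lists did not pass camera (limma adjusted p = 0.617, 0.922 and 0.922). The microRNA machinery list had a median of -0.05 and a mean of -0.01 against an upward direction of the test.

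Among 20 measured epithelial and clear cell carcinoma markers, 4 rose and 7 fell, with 4 and 7 adjusted over the list alone. KRT18, a keratin of simple epithelia, rose 2.33-fold from 5.53 ± 0.06 to 6.75 ± 0.11. MUC16, the mucin that carries the CA125 antigen, fell 2.45-fold from 11.43 ± 0.07 to 10.14 ± 0.29. The 1 other detected probe of KRT18 was also higher but did not pass. ANXA4, an annexin, and GPX3, a secreted glutathione peroxidase, fell 1.75-fold and 1.69-fold. Of 8 measured mesenchymal and fibroblast markers, 5 fell and 1 rose, with 5 and 1 adjusted over the list alone. LUM fell as given above, TAGLN, a smooth muscle actin-binding protein, rose 1.54-fold, and CDH2 and ACTA2, N-cadherin and smooth muscle actin, fell 1.37-fold and 1.30-fold, falls that did not pass with median scaling. Of 6 measured leukocyte, endothelial and red cell markers, 1 rose and 1 fell, with 1 and 1 adjusted over the list alone. PECAM1, an endothelial adhesion molecule, rose 1.36-fold from 4.79 ± 0.03 to 5.24 ± 0.13. VWF, von Willebrand factor, was not detected in the mimic arrays and was at least 1.23-fold lower there. KDR and CD79A differed by -0.21 and 0.20 without passing (limma adjusted p = 0.0655 and 0.0953), and passed without mir-100 mimic replicate 3 (0.0167 and 0.0334) and with array weights (0.00633 and 0.0326). With median scaling the epithelial list had 5 members higher and 4 lower with a median of 0.13, and the mesenchymal list 2 higher and 1 lower. The leukocyte, endothelial and red cell counts were 2 higher and 2 lower with array weights and without mir-100 mimic replicate 3, and 1 and 0 without each control mimic replicate. None of the 3 marker lists passed camera (limma adjusted p = 0.294, 0.134 and 0.922).

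In all, 6 of the 18 lists passed camera at its preset correlation, 0 passed with an estimated correlation (3 at an unadjusted p under 0.05) and 14 passed fry, all in limma. Other splits of the 6 arrays into 3 and 3 gave up to 8 lists at the preset correlation. Each of those splits kept part of the difference between the mimics, so their counts are not those of chance.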

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

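The test of the RNA-sensor genes below was chosen after the result was seen.

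Probes that carry no gene name entered none of the comparisons above. Of 5137 such probes that were detected, 1506 (29.3%) passed limma's adjusted threshold between the mimics, 710 higher and 796 lower in the mir-100 mimic arrays.

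Mir-100 mimic replicate 3 lay nearer to the control arrays than the other mimic arrays did, with a score of 19.8 against 25.8 and 27.6 on the first principal component. If its weaker signal had compressed dim genes, the ratio of its fold to that of replicate 2 would be lower for dim than for bright genes. The difference, bright minus dim, was -0.115 (95% bootstrap interval over genes -0.18 to -0.08), which argues against that. A candidate explanation that the test left open is that part of its RNA came from cells without the mimic effect: among genes at least 2-fold apart in replicate 1, and with replicate 2 as reference, those that rose needed a share of control signal of 12.3% (6.17 to 17.3, 147 genes) and those that fell 6.24% (4.01 to 7.81, 327 genes), and the intervals overlap. Whether such a mixture would lower the folds of bright genes more was not tested. A weaker response of the cells of replicate 3 was not tested either and stays open. The intervals in this paragraph resample genes of replicates 2 and 3, so they do not measure how arrays vary. Replicate 2, the reference, had the highest score on the first principal component.

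The G1/S and the G2/M lists lay higher in the mir-100 mimic arrays, which also had the higher mean signals. An intensity-dependent difference between arrays was tested against 10000 random lists matched on mean expression, and both lists lay at percentile 100, which argues against it. What stays open is an effect of mir-100 itself, an effect of the control mimic, and any difference between cultures or in array order that goes with the groups, none of which was tested.

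The NF-kB and inflammation list also lay higher. Its median was at percentile 99.7 of matched random lists, which argues against an intensity-dependent difference. A stronger RNA-sensor response to the mir-100 mimic was assumed, without a test, to raise interferon-induced genes by about as much as this list. The median of 7 such genes (RIGI, IFIH1, IFIT1, IFIT2, IFIT3, HERC5 and DDX60) was 0.0458 against 0.31 for the list. Its 95% bootstrap interval was -0.11 to 0.15, which resamples genes and does not measure how arrays vary. Only 2 of the 7 were detected on all 6 arrays. Genes so near the background cannot exclude a stronger RNA-sensor response, which stays open. An effect of mir-100 or of the control mimic also stays open and was not tested.

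For the number of changed genes, 1 of the 10 splits of the 6 arrays into 3 and 3 gave as many, the real one, with 6190 genes by limma against 0 at most in the others (6841 against at most 198 at an unadjusted p under 0.05). For the lists, 5 of the 10 splits, the real one among them, gave at least the real 6, and the highest of the others gave 8. Every other split puts mimic and control arrays in both groups, in unequal numbers. The difference between the mimics then adds to the spread within groups, so few genes can pass there in any case. For the lists, part of that difference stays between the groups. The splits therefore cannot tell whether either count exceeds chance. With 10 splits the share cannot fall under 0.05.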

How the results depend on the processing

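Cyclic loess normalization, a minimum fold of 2 and the test of every detected probe were chosen after the data were seen. MTOR kept its direction and side of the threshold in all 16 alternatives, with log2 differences from -0.97 to -0.57, and from -0.97 to -0.86 when each array was left out in turn. The count of changed genes stayed between 5284 and 7338 in the 16 alternatives at the same threshold with 1 value per gene, of which 8 tested other numbers of genes (10252 to 18852 in place of 12039), and between 5284 and 6304 without each array in turn, with 2607 to 3178 higher and 2626 to 3126 lower. Of the genes called, 4560 (73.7%) were shared with median scaling, and 83.9% to 98.4% with the others. Median scaling, which aligns the arrays on undetected probes, gave 4749 higher and 1461 lower, and 10 lists past the set test. With an estimated correlation 0 lists passed that test, and the target list at -0.46 had an adjusted p of 0.279. A fold of at least 1.5 left 1842 genes (802 higher, 1040 lower) and of at least 2 left 439 (128 and 311), or 58 and 184 without background correction and 72 and 194 with the authors' processed values. Every detected probe gave 9287 calls, 4864 higher, from 21361 tests.

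Only lists that never passed changed the direction of their set test. The p53 list had 0.252 with median scaling. The microRNA machinery list had -0.0531 without a detection filter, -0.0450 with array weights and -0.0716 to -0.00519 without each array in turn, turning without mir-100 mimic replicate 2. The unfolded protein response list had -0.0279 with cyclic loess and 0.0161 to 0.0713 without each array, turning without mir-100 mimic replicate 3. The leukocyte list had 0.0926 with the mean of a gene's probes and -0.0449 to 0.0864 without each array, turning without mir-100 mimic replicate 2 and without each control replicate. The direction is that of the set test, which can differ in sign from the median, and the cause was not tested. For named genes other than MTOR, 1408 of the values kept direction and side, 6 lost the call and 4 gained it. Small counts within lists also moved: 1 G1/S gene was lower with array weights and without control mimic replicate 3, 1 G2/M gene was lower without mir-100 mimic replicate 3, and 1 cholesterol gene was higher in 7 alternatives other than median scaling. The stricter filter left too few members of the leukocyte list for a set test.

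The replicate numbers did not pair the arrays: same-numbered arrays correlated in their deviations at -0.01, 0.02 and -0.05. With the replicate number as a block, 6082 genes changed, 3096 higher, and 6 lists passed. Not run were the seed-site test with all its alternatives and the chip as a block. Signal over background limits the dim genes, and detection in only 1 group gives bounds.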

Other observations

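The genes below were chosen after their values were seen. Some genes were detected in all arrays of 1 group and in none of the other, so that their folds are lower bounds. Not all of them passed limma's threshold, as with OPRL1 (adjusted p = 0.218) and CDH9 (0.110). The lowest bounds were 1.04-fold among genes seen only in mir-100 mimic arrays and 1.02-fold among those seen only in control arrays. In the mir-100 mimic arrays, 61 genes were seen that were in no control array. TGFBI, an extracellular matrix protein induced by transforming growth factor beta, was at least 2.73-fold higher there (limma adjusted p = 5.33e-08). IL4I1, a secreted amino acid oxidase, was at least 2.18-fold higher, IL15RA, a cytokine receptor subunit, at least 2.07-fold, H19, an imprinted long non-coding RNA, at least 1.88-fold, and S100A9, a calcium-binding protein of inflammation, at least 1.75-fold.

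In the control mimic arrays, 79 genes were seen that were in no mir-100 mimic array. FYB2 was at least 2.92-fold lower in the mir-100 mimic arrays (limma adjusted p = 5.33e-08), KCNJ13, a potassium channel, at least 2.496-fold, MTLN, a mitochondrial micropeptide gene, at least 2.30-fold, MAP1LC3A, a protein of autophagosome membranes, at least 2.19-fold, and SLC1A1, a glutamate transporter, at least 1.99-fold.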
